A study of Mus musculus with 2 samples.

How the data were processed

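RNA from dorsal root ganglia of wild-type mice was sequenced as 2 libraries, 1 from mice treated with acetone, ether and water (AEW) and 1 from mice treated with water. Per the labels' protocols, RNA was extracted with Trizol and each library was made from 500 ng of total RNA with a Lexogen QuantSeq kit. Per the series' design text, RNA of 6 mice per group was pooled, which is read here as 1 pool for each library. The submitters' processing notes name Bowtie2, bedtools and genome build mm10. Tool versions, the gene annotation, the use of strand, the treatment of reads with several matches and the treatment of duplicate reads are not given in the sources used here. Whether reads came only from the 3' ends of transcripts is likewise not given.

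The deposited files hold whole-number read counts per gene symbol, not normalized, with 23282 rows per library in the same order. The control total was 9333882 counts and the AEW total 14376228. The 10 most abundant rows took 18.9% of the control counts and 12.5% of the AEW counts. Rn45s, a ribosomal RNA row, took 5.77% of the control counts and 4.03% of the AEW counts. A total of 35 symbols occurred more than once, over 79 rows with 0.186% of the control counts and 0.196% of the AEW counts. These rows stayed in the library totals and were left out of calls and lists. No row had a mitochondrial symbol, so a planned list of mitochondrial transcripts had no member.

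Library sizes were scaled with TMM in edgeR 4.0.16 under R 4.3.3, which gave factors of 0.970 for the control and 1.03 for the AEW library. Scaled CPM (count divided by the scaled library size and multiplied by 10 to the power of 6) and the AEW to control ratio were computed from the deposited counts with these sizes. Each ratio has an exact 95% interval from the conditional binomial distribution (Clopper-Pearson). A gene was measured when its summed count was at least 20. It was called higher or lower in the AEW library when the ratio was at least 1.5-fold and the interval excluded 1. With 1 library per group there was no test across animals and no p-value was computed. Reads carried no molecular identifiers in the deposited values, so intervals and floors cover counting error only, and reads amplified from the same molecule are not independent. A count of 0 allows up to 3 counts per library, which is 0.331 CPM in the control and 0.202 CPM in the AEW library, and a fold against 0 was computed against that floor. A gene with 1 to 3 counts is given with its counting interval.

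Gene lists for receptors, channels, peptides, injury, immune, metabolic and cell type programmes were written before the data were examined, as were the calling rule, the named-gene rule and 10 checks with other settings. Of 999 listed symbols, 991 matched a row and 3 matches used an older symbol. Ribosomal proteins were taken by name prefix, without kinases and pseudogenes of similar name. For each of 42 lists with measured members, the median log2 ratio was set against 10000 random lists of the same size, matched on mean expression within 100 ranks on each side. A list stood apart when its percentile was under 1 or over 99. The share of library counts that a list takes has an exact binomial (Clopper-Pearson) interval. Further lists of pigment cell, sebaceous gland, epidermal, keratin family and dermal genes were written after the leading genes had been seen.

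Genes are named by a fixed rule. It takes the 12 genes with the highest lower bound of the ratio interval and the 12 with the lowest upper bound among measured genes with a summed count of at least 50, without uncharacterised gene models, clone names and small RNAs. It adds up to 4 members per described list, namely those with the 2 highest lower bounds and the 2 lowest upper bounds. It always includes Nppb, Sst, Il31ra, Mrgpra3, Mrgprd, Trpv1, Trpa1, Hrh1, Tac1, Calca, Atf3 and Gal. The values of some genes that the rule takes are not reported here. Any other named gene is said to have been chosen after its values were seen. Symbols were matched to GENCODE M21 for gene identifiers and coordinates, which are 1-based on mm10.

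The calling step was tested on simulated data for the same comparison. With sampling noise alone, 100 of 14868 genes were called higher and 77 lower. Of 100 genes doubled in a simulation of 14859 genes, 94.0% were called higher, and of 100 genes at 0.5 times the control level, 85.0% were called lower. The interval held the true ratio for 96.0% of genes. Of 100 random lists of 30 genes without a shift, 2 stood apart, and of 20 lists shifted by 0.5 on the log2 scale, 17 did.

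The calls and lists were repeated with DESeq2 1.42.0 size factors, total count scaling, upper quartile scaling, no filter on low counts, a summed count of at least 100, the AEW library thinned to the control total, an interval that excludes 1.5-fold, a distance of over 3 scaled median absolute deviations from the 500 genes nearest in mean expression, log2 of CPM plus 1 for lists, and totals and lists without ribosomal protein and haemoglobin genes. Checks made for normalized values did not apply. A further 5 checks were added after the data were seen. These were a spline correction for GC content of the last 500 bases and length of the longest annotated transcript, the same with GC content of the whole transcript, scaling on the median of the pan-neuronal marker list, counts without skin genes, and lists without the members shared by the injury and neuropeptide lists. GC content was known for 95.4% of measured genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, patsy 1.0.2 and matplotlib 3.10.9 were used.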

Results

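Gene expression was measured by RNA sequencing in mouse dorsal root ganglia, which hold the cell bodies of the sensory neurons that serve the skin. Dry skin was produced with acetone and ether followed by water (AEW), a chemical model of dry-skin itch, on 5 days in a row, and ganglia were taken on day 6. Controls received water. RNA of 6 mice was pooled in each group and sequenced as 1 library, so no difference given here has a replicate check. The control library held 9333882 counts and the AEW library 14376228 counts, a ratio of 1.54. At least 1 count was present for 17182 rows in the control and 17485 rows in the AEW library.

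The comparison asks how dry skin alters expression in the ganglia. Several genes of itch neurons and non-peptidergic neurons were higher in the AEW library, led by Mrgpra3, a receptor of pruritogens in itch neurons, at 4.93-fold (95% counting interval 4.07 to 6.03), Sst, the somatostatin gene, at 4.71-fold (3.39 to 6.69) and Mrgprd, the beta-alanine receptor, at 4.37-fold (3.94 to 4.85), although the list of itch neuron markers had a median log2 ratio of 0.01 and includes Nts, which was lower. Ion channels were higher as groups, with 29 of 57 measured voltage-gated channel subunits and 15 of 31 sensory transduction channels called higher, beside 12 of 22 pan-neuronal markers. The medians of both channel lists lay below 0 when scaled on those markers. When a distance of over 3 scaled median absolute deviations was also required, 4 voltage-gated subunits, 0 transduction channels and 1 pan-neuronal marker stayed called higher. Macrophage markers were lower, 25 of 28, and so were 19 of 37 genes linked to nerve injury, with Gal 6.00-fold (5.57 to 6.47), Nts 6.74-fold (6.15 to 7.39) and Atf3 4.63-fold (3.75 to 5.74) lower. With the deviation limit, 6 macrophage markers and 6 injury genes stayed called lower. Keratin and cornified-envelope genes together had 443 counts in the control library and 40296 in the AEW library. Whether skin or hair follicle RNA had entered the AEW sample could not be decided, so these genes cannot be read as a response of the ganglia.

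Of 14854 measured genes, 2577 (17.3%) were called higher in the AEW library, 2220 (14.9%) lower and 10057 neither. At 2-fold, 1223 were higher and 1018 lower. The median log2 ratio over measured genes was 0.03, with quartiles at -0.39 and 0.43. Across measured genes, log2(CPM + 1) of the 2 libraries had a Pearson correlation of 0.937, where genes are not independent replicates. The counting interval compares these 2 libraries and not the treatments, and with 1 pool per group the treatment cannot be told apart from differences between animals, dissections or library preparation. Scaling on the pan-neuronal marker list, a choice made after the data were seen, moved the median of all genes by -0.68 on the log2 scale and gave 651 genes higher and 7662 lower.

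**Figure D1:**
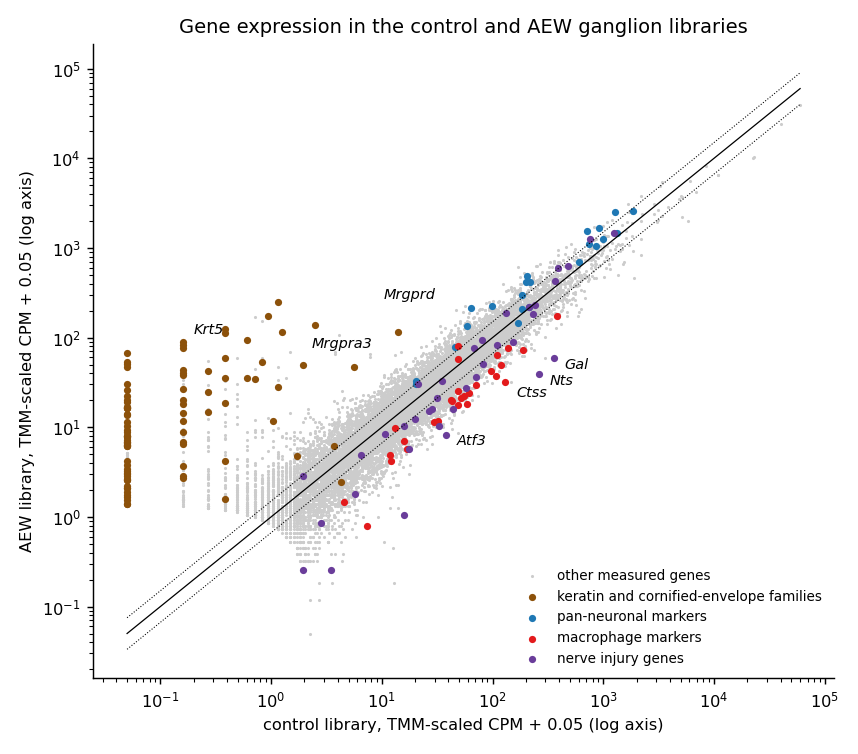
Each point is a measured gene, with TMM-scaled CPM plus 0.05 in the control library on the horizontal log axis and in the AEW library on the vertical log axis; the solid line marks equal levels and the dotted lines 1.5-fold differences. Keratin and cornified-envelope genes lie mostly toward the left edge, with Krt5 at 0.110 CPM in the control and 90.1 CPM in the AEW library, pan-neuronal markers lie mostly above the line and macrophage markers mostly below it.

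Receptors of itch-inducing and inflammatory ligands moved in both directions. Of 34 measured members, 9 were higher, 5 lower and 20 neither, with a median log2 ratio of 0.18 that did not stand apart from random lists (percentile 88.5). Mrgpra3 (ENSMUSG00000078698.3, chromosome 7, 47588950 to 47601372, minus strand) had 118 counts in the control and 953 in the AEW library. Mrgprd (ENSMUSG00000051207.7, chromosome 7, 145314835 to 145324086, plus strand) had 420 and 3004 counts. Mrgpra3 has close relatives in the genome, and how reads with several matches were counted is not given in the sources used here. Il31ra, the receptor chain for the itch cytokine interleukin 31 (ENSMUSG00000050377.8, chromosome 13, 112519898 to 112594360, minus strand), was 2.27-fold higher (1.83 to 2.84). Hrh1, a histamine receptor, had a ratio of 0.97 (0.65 to 1.47) at 41 and 65 counts. Il1rl1, the interleukin 33 receptor, was 2.49-fold lower (1.66 to 3.77) and Tlr3, a receptor for double-stranded RNA, 1.99-fold lower (1.52 to 2.60). For Mrgprx1, 0 and 3 counts allowed no comparison.

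**Figure D2:**
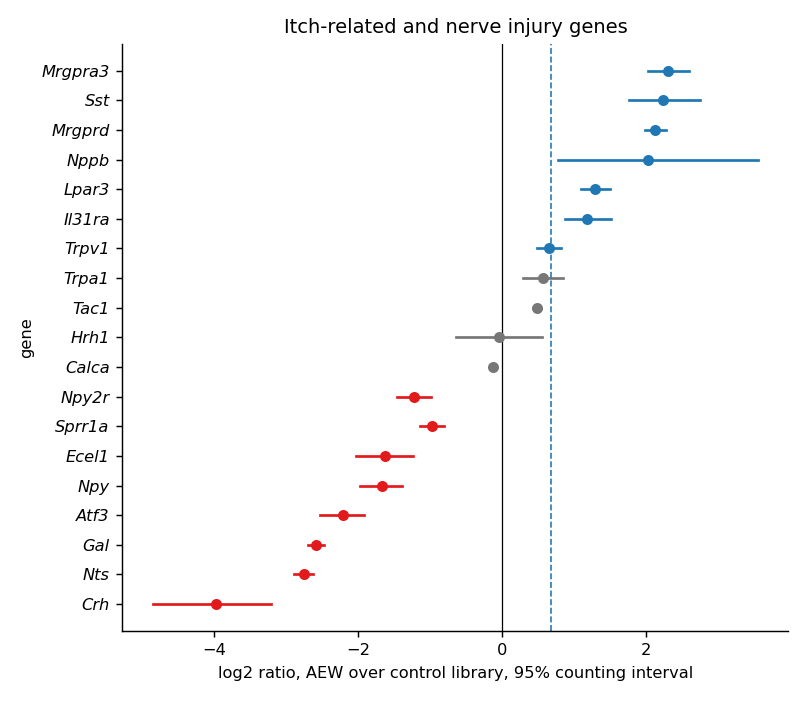
Log2 ratio of the AEW over the control library for itch-related and nerve injury genes (points) with 95% counting intervals (bars); the solid line marks equal levels and the dashed line the pan-neuronal marker median of 0.68. Mrgpra3 at 2.30 and Mrgprd at 2.13 lie above the dashed line, Trpv1 at 0.65 lies on it, and Gal at -2.59 and Crh at -3.97 lie below 0.

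Among channels that transduce chemical, thermal and mechanical stimuli, 15 of 31 were higher, 3 lower and 13 neither, with a median log2 ratio of 0.57 (percentile 100). Kcnk18, the potassium channel TRESK, was 4.52-fold higher (2.63 to 8.35) and the ATP-gated channel subunit P2rx6 3.51-fold (2.40 to 5.29). Trpv1, the capsaicin receptor, was 1.57-fold higher (1.40 to 1.76), a difference that was not called after correction for whole-transcript GC content. Trpa1, the receptor of mustard oil and a channel used by several itch pathways, had a ratio of 1.48 (1.23 to 1.79), just under the threshold, and passed it under total count scaling at a log2 ratio of 0.65. Piezo1, a mechanically gated channel, was 1.73-fold lower (1.46 to 2.06) and Trpm3, a heat-activated channel, 1.71-fold lower (1.32 to 2.21). Trpm8, the cold receptor, had 0 and 2 counts. Voltage-gated sodium, potassium, calcium and HCN channel subunits were higher in 29 of 57, lower in 2 and neither in 26, with a median log2 ratio of 0.60 (percentile 100). Kcnab2 and Kcnip1, auxiliary subunits of potassium channels, were 3.16-fold (2.97 to 3.38) and 3.23-fold (2.82 to 3.71) higher. Kcnd2, a pore subunit of A-type potassium channels, was 1.74-fold lower (1.16 to 2.61) but not called after the GC correction, and Cacna2d1, the gabapentin-binding calcium channel subunit, had a ratio of 0.79 (0.74 to 0.83).

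The channel lists moved with markers of neurons in general. Of 22 pan-neuronal markers, 12 were higher, none lower and 10 neither, with a median log2 ratio of 0.68 (percentile 100), and they took 1.06% (1.06 to 1.07) of counts in the control and 1.73% (1.72 to 1.74) in the AEW library. Rbfox3, which encodes the neuronal nuclear antigen NeuN, was 3.31-fold higher (3.03 to 3.62) and Avil, an actin-binding protein of sensory neurons, 2.36-fold (2.24 to 2.48), whereas Map2 had a ratio of 0.86 (0.80 to 0.92) and Gap43 of 1.05 (0.99 to 1.11). Scaled on the pan-neuronal list, the median of the sensory transduction channels was -0.11, that of the voltage-gated channels -0.07 and that of the neuropeptides -0.19, so the sign of these medians turned. That scaling lowers each log2 ratio by the same 0.68, also in the random lists, so it cannot change whether a list stands apart. On that scale Mrgpra3 stayed at a log2 ratio of 1.63, Sst at 1.56, Mrgprd at 1.45 and Nppb at 1.35, all still called higher, while Il31ra at 0.51 and Trpv1 at -0.02 were not called.

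The median of each of 6 neuron classes was set against that of the pan-neuronal markers, a comparison chosen after the data were seen, and every bootstrap interval over genes included 0. The differences were 0.05 (-0.39 to 0.71) for Mrgprd neurons, -0.46 (-0.86 to 0.06) for peptidergic, -0.39 (-0.76 to 0.03) for large myelinated, -0.66 (-1.26 to 0.40) for itch, -0.20 (-1.15 to 0.70) for C-fibre mechanoreceptor and -0.63 (-1.86 to 0.45) for cold-sensing neurons. Markers of Mrgprd-expressing non-peptidergic neurons were higher in 7 of 12, lower in 1 and neither in 4, with a median log2 ratio of 0.73 (percentile 100). In this list the lysophosphatidic acid receptor Lpar3 was 2.45-fold higher (2.13 to 2.82) and Ret, a receptor tyrosine kinase, 1.57-fold lower (1.47 to 1.67), a call that was lost after the GC correction and under total count scaling. The list of Mrgpra3 and Nppb/Sst itch neurons had a median of 0.01 (percentile 51.7), and its members went both ways, with 5 of 14 higher, 2 lower and 7 neither. Besides Mrgpra3, Sst and Il31ra, Nppb, the natriuretic peptide of itch neurons (ENSMUSG00000029019.8, chromosome 4, 147985788 to 147987205, plus strand), was 4.07-fold higher (1.72 to 11.8) at only 6 and 40 counts. Nts, the neurotensin gene, and Npy2r, a receptor of neuropeptide Y, were lower, the latter 2.33-fold (1.98 to 2.75). Of 13 peptidergic nociceptor markers, 3 were higher, 1 lower and 9 neither (median 0.22, percentile 88.0, or 0.42 and 98.88 after the GC correction). Gfra3, a receptor for artemin, was 1.57-fold higher (1.41 to 1.75), not called after either GC correction and at -0.03 on the log2 scale with pan-neuronal scaling, whereas Calca, the gene of calcitonin gene-related peptide, had a ratio of 0.91 (0.90 to 0.93). Markers of C-fibre low-threshold mechanoreceptors were higher in 4 of 9 and lower in none (median 0.47, percentile 96.6), with Th, tyrosine hydroxylase, 3.44-fold higher (3.06 to 3.87) and Pou4f2 2.24-fold higher (1.59 to 3.22). Markers of large myelinated neurons were higher in 7 of 20 and lower in none (median 0.28, percentile 95.4). Of 4 measured markers of cold-sensing neurons, 1 was higher, Gsg1l, 1 was lower, Foxp2, and 2 were neither (median 0.04, percentile 58.2).

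Neuropeptide precursors divided into a higher and a lower set. Of 25 measured, 8 were higher, 6 lower and 11 neither, and the median log2 ratio of 0.49 stood apart (percentile 99.9). Sst (ENSMUSG00000004366.4, chromosome 16, 23889573 to 23890958, minus strand) had 41 and 316 counts, and Pcsk1n, a granin-like precursor, was 2.59-fold higher (2.38 to 2.83). Crh, the gene of corticotropin-releasing hormone (ENSMUSG00000049796.4, chromosome 3, 19693401 to 19695396, minus strand), was 15.7-fold lower (9.22 to 28.8) at 144 and 15 counts. Tac1, the substance P gene, had a ratio of 1.40 (1.35 to 1.46).

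Genes known to rise in sensory neurons after nerve injury were lower by their median ratio. Their share of library counts went the other way, with 0.551% (0.547 to 0.556) in the control and 0.616% (0.612 to 0.620) in the AEW library. Of 37 measured, 19 were lower, 2 higher and 16 neither, with a median log2 ratio of -0.62 (percentile 0). Gal, the galanin gene (ENSMUSG00000024907.7, chromosome 19, 3409915 to 3414544, minus strand), had 357.5 CPM in the control and 59.6 CPM in the AEW library, and Nts (ENSMUSG00000019890.4, chromosome 10, 102481756 to 102490486, minus strand) had 261 and 38.7 CPM. Atf3, a transcription factor induced in injured neurons (ENSMUSG00000026628.13, chromosome 1, 191170296 to 191218039, minus strand), had 38.1 CPM in the control and 8.23 CPM in the AEW library. The exceptions were Anxa2 at 1.64-fold (1.59 to 1.69) and Basp1 at 1.55-fold (1.49 to 1.61) higher. Anxa2 was not called after the GC correction on the last 500 bases, and Basp1 was not called after that on the whole transcript and had a log2 ratio of -0.05 when scaled on the pan-neuronal list. Immediate early genes, which respond to recent activity, were lower in 9 of 32 and higher in none (median -0.31, percentile 0.3), and the list no longer stood apart after the GC correction (median -0.24, percentile 1.12). Nr4a3 was 7.57-fold lower (4.84 to 12.3) and Fosb 2.53-fold lower (1.72 to 3.75).

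Receptors that dampen sensory neuron activity were higher in 5 of 20, lower in 1 and neither in 14 (median 0.25, percentile 90.03). The adenosine receptor Adora1 was 2.39-fold higher (2.12 to 2.71) and the GABA-B receptor subunit Gabbr1 1.80-fold (1.68 to 1.93). Of 20 receptors of neurotrophic factors, 5 were higher, 4 lower and 11 neither (median -0.08, percentile 17.9). Ngfr, the low-affinity neurotrophin receptor, was 2.69-fold higher (2.55 to 2.84), Csf1r, the macrophage growth factor receptor, 2.58-fold lower (2.39 to 2.79) and Met 2.13-fold lower (1.65 to 2.75).

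Transcripts of immune cells were lower in the AEW library. Macrophage markers had a median log2 ratio of -1.29 (percentile 0), with 25 of 28 lower, 1 higher and 2 neither, and their share of counts was 0.194% (0.191 to 0.196) in the control and 0.0971% (0.0955 to 0.0987) in the AEW library. Ms4a7, a macrophage membrane protein, was 9.82-fold lower (5.15 to 20.6) and Ctss, a lysosomal protease, 4.11-fold lower (3.69 to 4.58), while Lgmn, a further lysosomal protease, was 1.66-fold higher (1.48 to 1.85). Neutrophil markers were lower in 11 of 13 and higher in 1 (median -1.46, percentile 0), with S100a9 3.39-fold lower (3.24 to 3.56) and Lcn2 3.60-fold lower (3.004 to 4.32). Mast cell markers were lower in 6 of 7 (median -1.31, percentile 0.01), with the tryptases Tpsab1 5.95-fold (4.24 to 8.51) and Tpsb2 4.56-fold (3.75 to 5.57) lower. Of 6 measured lymphocyte markers 1 was lower, Cd79b, and the median of -0.83 lay at percentile 7.24. Cytokines, chemokines and inflammatory mediators were lower in 21 of 36 and higher in 2 (median -0.77, percentile 0), with the chemokine Ccl5 11.4-fold lower (6.91 to 19.8), Ccl24 5.20-fold lower (2.97 to 9.57) and Ccl8 2.02-fold higher (1.38 to 3.05). Interferon-stimulated genes were lower in 15 of 49 and higher in 2 (median -0.34, percentile 0.14). Irf8 was 3.55-fold lower (2.84 to 4.46), whereas Oasl2, an antiviral gene, was 2.31-fold higher (1.84 to 2.92).

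Among the 12 lowest genes of all, Mmp12, a macrophage metalloproteinase, had 117 counts in the control and 2 in the AEW library, a ratio of 95.8-fold lower with a counting interval of 25.9 to 800.0. Wfdc3 was 30.8-fold lower (13.7 to 85.8) and Saa3, an acute-phase protein, 22.0-fold lower (10.3 to 56.2). Ttr, the thyroxine carrier transthyretin, was 9.64-fold lower (5.81 to 16.9), Cbln3 10.8-fold (5.12 to 26.4) and Trim63, a muscle ubiquitin ligase, 9.82-fold (5.54 to 18.7). The other 6 were Crh, Ccl5, Nts, Gal, Ms4a7 and Nr4a3, described in their lists.

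Connective tissue, muscle and blood transcripts were lower as well. Of 43 extracellular matrix genes, 21 were lower, 1 higher and 21 neither (median -0.58, percentile 0), with Lum 2.88-fold (2.73 to 3.04) and Dcn 2.34-fold (2.31 to 2.37) lower, both proteoglycans, and Mmp3 3.67-fold higher (1.41 to 12.1) at 5 and 30 counts. Fibroblast markers were lower in 12 of 19 and higher in none (median -0.77, percentile 0), with Apod 2.92-fold lower (2.87 to 2.96) and Col1a1 at a ratio of 0.99 (0.96 to 1.02). Skeletal muscle markers were lower in 11 of 16 and higher in none (median -1.18, percentile 0), with Actn3 3.82-fold lower (3.17 to 4.61) and the myosin Myh4 2.95-fold lower (2.79 to 3.12). Red blood cell markers, which took 6.80% (6.78 to 6.81) of control counts and 4.33% (4.32 to 4.34) of AEW counts, were lower in 8 of 11 (median -0.74, percentile 0.07). Hbb-b1 and Hbb-bs had nearly equal counts, 98099 and 99044 in the control and 95624 and 96798 in the AEW library. Counts of Hbb-b2 and Hbb-bt were also close. These pairs are uncertain as separate genes, so the shares and the number lower may hold the same reads under different names. The list did not stand apart when ribosomal protein and haemoglobin genes were left out of the totals and of the list (median -0.57, percentile 2.06). Mural cell markers were lower in 6 of 14 (median -0.54, percentile 0.04), with Acta2, smooth muscle actin, 2.26-fold lower (2.06 to 2.49). Endothelial markers did not stand apart, with 4 of 17 lower and 13 neither (median -0.12, percentile 16.7, or -0.31 and 1.31 after the GC correction). Nor did adipocyte markers, with 4 of 12 higher and 8 neither (median 0.12, percentile 72.3). Markers of spinal cord cells were lower in 7 of 16 (median -0.59, percentile 0.62), with Slc32a1 2.66-fold lower (1.83 to 3.89).

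Glial markers showed smaller differences. Satellite glia markers were lower in 4 of 16 and neither in 12 (median -0.35, percentile 1.78, or 0.31 after correction for whole-transcript GC content), with Ednrb 2.55-fold lower (2.36 to 2.77). Myelinating Schwann cell markers were lower in 4 of 21 and neither in 17 (median -0.30, percentile 1.24), and Ugt8a was 2.16-fold lower (2.04 to 2.29). This list lay under percentile 1 after thinning (median -0.34, percentile 0.81) and after the GC correction (median -0.30, percentile 0.36). Of 9 markers of non-myelinating Schwann cells, 3 were higher, 2 lower and 4 neither (median -0.18, percentile 16.7), with L1cam 1.73-fold higher (1.60 to 1.87) and Matn2 1.95-fold lower (1.83 to 2.09).

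**Figure D3:**
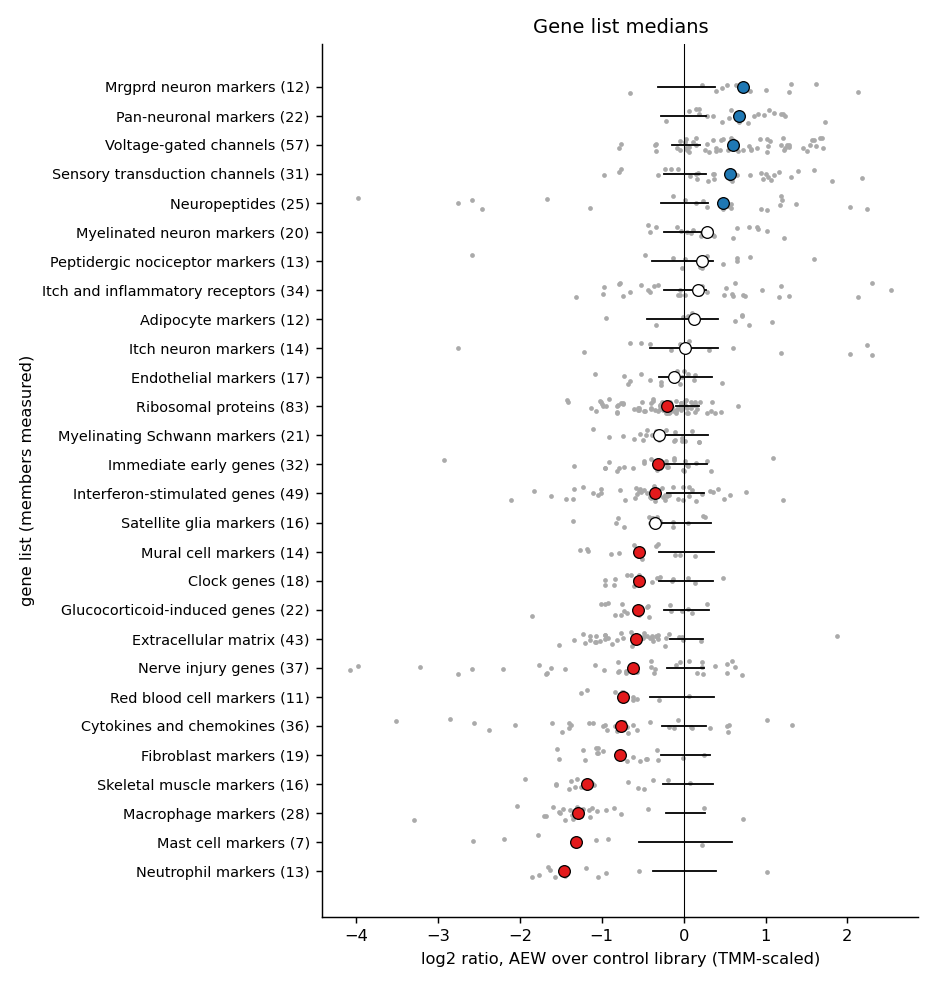
Log2 ratio of the AEW over the control library for the measured members (grey points) and the median (large point) of gene lists, with the middle 95% of medians of matched random lists as black bars; filled large points mark lists that stood apart, blue higher and red lower. Without the keratinocyte and other skin lists, which are not drawn, medians run from 0.73 for Mrgprd neuron markers to -1.46 for neutrophil markers, and scaling on the pan-neuronal list would place those of the voltage-gated channels, sensory transduction channels and neuropeptides below 0.

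Keratinocyte markers were higher in 9 of 9, with a median log2 ratio of 4.72 (percentile 100). Krt5 (ENSMUSG00000061527.7, chromosome 15, 101707070 to 101712898, minus strand) and Krt14 (ENSMUSG00000045545.8, chromosome 11, 100203162 to 100207548, minus strand), the keratins of basal epidermis, had 1 count each in the control and 1336 and 1218 counts in the AEW library, ratios of 816 (146 to 32262) and 744 (133 to 29414). In this list, Krt10, a keratin of upper epidermis, was 8.19-fold higher (6.84 to 9.89) and Perp, a desmosomal protein, 4.65-fold (3.88 to 5.61). The 12 highest genes of all were all keratins, keratin-associated proteins or the hair follicle protein Tchh. The hair keratin Krt81 had 10 and 3688 counts, a ratio of 225 (122 to 470), and Tchh had 6 and 2538 counts, a ratio of 258 (119 to 705). Krtap22-2 had 0 and 1008 counts, at least 205-fold higher against the floor of 3 counts per library, Krtap3-1 at least 161-fold, Krtap11-1 at least 155-fold and Krt31 at least 142-fold. The others were Krt15, Krt17, Krt71 and Krtap8-1, with 3, 3, 1 and 8 counts in the control library. Keratin-associated genes form families of similar sequence, so the division of reads among their members is uncertain. In lists written after these genes had been seen, 93 of 94 measured keratin and cornified-envelope family members were higher and 1, Krt19, lower. The family list has 141 members. Those near absent from the control library were measured only when high in the AEW library, so this share is no measure for the family. Some were clearly present in the control library, such as Krt10 with 127 counts and Krtdap with 50 counts. With genes at 0 set to their bound, their median log2 ratio was 5.07, and they took 0.00475% (0.00431 to 0.00521) of control counts and 0.280% (0.278 to 0.283) of AEW counts. Of 35 other epidermal genes 31 were higher, and of 10 sebaceous gland genes 7 were higher, as was 1 of 5 pigment cell genes, while of 12 dermal genes 3 were lower and none higher. Dermal genes such as Dcn, with 46855 counts in the control library, would hide a small amount of skin, so they cannot show its absence.

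Several housekeeping programmes were also compared. Glucocorticoid-induced genes were lower in 9 of 22 and higher in none (median -0.55, percentile 0), beside lower neutrophil and fibroblast markers. The lowest member, Lcn2, is also in the neutrophil list, Per1, 1.95-fold lower (1.66 to 2.30), is also a clock gene, and Ddit4 was at a ratio of 1.04 (0.97 to 1.12). Circadian clock genes were lower in 8 of 18 and higher in none (median -0.55, percentile 0.05), with Per2 1.94-fold lower (1.72 to 2.20) and Nr1d1 at a ratio of 1.39 (1.20 to 1.63). Ribosomal protein genes were lower in 18 of 83 and higher in 1 (median -0.21, percentile 0.01), with Rps14 2.66-fold lower (2.60 to 2.72). Nuclear-encoded respiratory chain genes did not stand apart, with 5 of 76 higher and 11 lower (median 0.07, percentile 70.3), although Cox7b was 4.09-fold lower (3.98 to 4.21) and Cox6c 2.74-fold lower (2.66 to 2.82). Heat shock and unfolded protein response genes were higher in 4 of 31 and lower in 2 (median 0.19, percentile 92.9), with Hsp90ab1 1.74-fold higher (1.71 to 1.76). Cholesterol synthesis genes were higher in 5 of 24 and lower in 1 (median 0.20, percentile 90.6), with the sterol regulator Srebf2 2.61-fold (2.06 to 3.33) and the enzyme Dhcr7 2.38-fold (2.03 to 2.80) higher. Proliferation genes were higher in 2 of 29 and lower in 5 (median -0.13, percentile 22.6), with Hmgb2 2.21-fold lower (1.68 to 2.91).

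As checks of the samples, Y-linked genes and Xist were compared, and both libraries showed Y-linked transcripts with few Xist counts, 11 in the control and 4 in the AEW library. The sex marker list had 2 of 4 measured members lower (median -0.56, percentile 3.88), with Kdm5d 1.84-fold lower (1.35 to 2.51). Nuclear long non-coding RNAs were higher in 2 of 8 and lower in 3 (median -0.09, percentile 30.6), with Neat1 2.30-fold lower (2.24 to 2.36) and Snhg11 1.80-fold higher (1.73 to 1.87). The log2 ratio was related to GC content across 14176 genes (Spearman 0.225, across genes that are not independent), from a median of -0.24 in the 10% of genes lowest in GC to 0.30 in the 10% highest. After correction for GC content and transcript length, 2259 genes were higher and 2068 lower of 14310, and 2040 and 1792 of them were called in the same direction without it. The correction left 6 lists apart on the higher side and 16 on the lower side, the same numbers as before it. Random lists of unrelated genes would give 0.84 of 42, but genes of a list can move together and some lists share members.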

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

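The 2 corrections for GC content and length, scaling on the pan-neuronal list, counts without skin genes and lists without shared members were chosen after the data were seen. No paired analysis was possible because each group had 1 library, and for the same reason no replicate could be left out. Counts of calls stayed within 1.5 times the reported ones under all scalings except that on the pan-neuronal list, and under both low-count filters, thinning, both GC corrections and both removals of genes. A total of 4797 genes were called either way; 2398 had an interval that excluded 1.5-fold (1327 higher and 1071 lower), and 428 lay over 3 median absolute deviations from their neighbours (332 higher and 96 lower), where the share of calls that were higher was 77.6% against 53.7%. In that last rule, genes at 0 in either library have no deviation and were kept, and without them 197 were higher and 95 lower. Scaling on the pan-neuronal list gave 8313 calls (651 higher and 7662 lower, 7.83% higher), which follows from a shift of every ratio by the same amount.

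Of 42 lists, those whose standing changed were immediate early genes after the GC correction on the last 500 bases (-0.24), red blood cell markers without ribosomal protein and haemoglobin genes (-0.57), and myelinating Schwann cell markers, which came to stand apart after thinning (-0.34), after that correction (-0.30), without ribosomal protein and haemoglobin genes (-0.30) and with GC content of the whole transcript (-0.32), as did satellite glia markers with the latter (-0.42). Leaving out haemoglobin genes takes them out of the red blood cell list itself. The cause was not tested for the other lists. Scaled on the pan-neuronal list, the medians of sensory transduction channels (-0.11), voltage-gated channels (-0.0732) and neuropeptides (-0.19) changed sign, because each log2 ratio is lowered by the same 0.68. Their percentiles cannot change under that shift, since the random lists move alike. On that scale the sign also changed for named genes such as Trpv1 (-0.0246), Basp1 (-0.0457), Gfra3 (-0.0293), Fabp4 (-0.0532), Rpl29 (-0.00749), Gap43 (-0.61), Ddit4 (-0.62), Cry2 (-0.62) and Myh1 (-0.59). Of 200 named genes, 108 kept their standing when the deviation limit was added and 92 lost a call, among them Nppb and Il31ra. The GC correction on the last 500 bases ended the calls of 6 named genes, namely Kcnd2, Anxa2, Rpl29, Ret, Gfra3 and Ddx3y, and added those of Trpa1 and Cd79a. Correction for whole-transcript GC content ended those of Trpv1, Basp1, Rpl29, Gfra3, Chl1, Ddx3y and Snhg14 and added those of Trpa1 and Tac1. Depth limits genes with few counts, and Mrgprx1, Trpm8 and most lymphocyte markers were under or near the measured minimum of 20.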

Other observations

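The test of the macrophage against the endothelial median was chosen after the result was seen, as were the GC and length corrections, of which that for the whole transcript was the last, the skin lists and the genes in the next 2 paragraphs.

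Among genes with at least 100 counts in the control library, several outside the lists were among the highest. Cntn2, an axonal adhesion molecule, was 4.01-fold higher (3.65 to 4.41) and Dpp6, a partner of A-type potassium channels, 3.59-fold (3.26 to 3.95). Elovl4, which elongates very long fatty acids, was 4.01-fold higher (3.55 to 4.54). Mapt, the tau gene, was 2.78-fold higher (2.64 to 2.93). Gpha2, a glycoprotein hormone subunit, was 3.35-fold higher (2.96 to 3.79). The overlapping genes Snrpn and Snurf were 2.54-fold (2.42 to 2.66) and 2.52-fold (2.40 to 2.64) higher and cannot be counted apart.

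Some genes outside the lists were lower. Cwc22, a splicing factor, was 4.97-fold lower (4.61 to 5.37) and Pop4, a subunit of ribonuclease P, 5.63-fold lower (4.61 to 6.92). Lrrc17 and Akap5 each took over 2% of control counts and about 1% of AEW counts (2.23% and 2.20% against 1.06% and 1.04%). Their counts were nearly equal in each library, so they are uncertain as separate genes.

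Keratin, hair shaft and other epidermal genes were higher in the AEW library, and many were near absent from the control library. To check the greater depth of the AEW library, it was thinned to the control total. All 31 of 31 epidermal genes outside the keratin family (100%) stayed called higher. These were chosen as called higher, and their list had a median log2 ratio of 4.20 with genes at 0 set to their bound. Thinning at a depth ratio of 1.54 could hardly end such calls, so this check decides little. Skin or hair follicle RNA in the sample could bring pigment cell and sebaceous gland genes too. Of 13 measured genes of these cells, 6 (46.2%) were higher, a share between the limits set beforehand for presence and absence. All 6 were sebaceous gland genes, so the share joins lists that differed. Keratin-type expression in ganglion cells without other skin cells cannot be told apart from it by that share (46.2%), because genes such as Pmel, with 421 control counts, would hide a small amount of skin, and genes with few control counts, such as Elovl3 at 46.6-fold higher (18.0 to 172), are measured mainly when high in the AEW library. Among genes already seen when the lists were written, Awat1 was at least 45.6-fold and Dct at least 58.4-fold higher, and whether skin entered at dissection or between libraries was not tested.

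Neuronal genes were higher while macrophage, connective tissue and muscle genes were lower. The trend with GC content is argued against, because after correction for the last 500 bases the pan-neuronal median was 0.67 against 0.68 and the macrophage median -1.36 against -1.29, and after correction for the whole transcript, apt if reads are not from 3' ends, they were 0.58 and -1.30. A higher share of neurons could lower other cell types alike, but the macrophage median lay below the endothelial one, with a difference of -1.18. Its bootstrap interval (-1.35 to -0.76) resamples genes that are not independent and does not cover differences between animals. After the GC correction on the last 500 bases these medians were -1.36 and -0.31. Part of the pattern may still come from a higher share of neurons, from cleaner dissection with less muscle, blood and sheath, or from fewer immune cells after treatment. These cannot be separated with 1 pool per group.

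Nerve injury genes were lower in the AEW library by their median ratio, but not by their share of counts, although neuronal genes were higher. After correction for GC content and length their median was -0.53 against -0.62, and -0.62 with GC content of the whole transcript, so that trend is argued against as the whole cause. The nerve injury median minus the pan-neuronal one was -1.30 (bootstrap interval over genes -1.72 to -0.76), a comparison without a prediction set beforehand. It cannot decide whether a higher share of neurons is the whole cause, because the injury list was not limited to genes that only neurons express. Csf1 and Il6, for example, are also in the cytokine list, and Gap43 is in both lists compared. The interval does not cover differences between animals. Injury of sensory neurons in the control mice and a lowering by the AEW treatment were not tested.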
